A study of Caenorhabditis elegans with 6 samples.

How the data were processed

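Poly(A)-enriched RNA of whole C. elegans was sequenced with paired reads of 150 bases in 6 libraries, per the series design text and the labels' protocols. The groups, 3 control and 3 ethyl carbamate libraries (100 mM, 24 h), come from the treatment label, and the design text states that the replicates are biological. The titles of the control samples carry the prefix EV and those of the exposed samples do not, while the descriptions and column names carry it for both groups. The sources used here do not explain it. The submitters' processing notes name HISAT2 2.0.5, featureCounts 1.5.0-p3, StringTie 1.3.3 and DESeq2 1.20.0, while the design text names DEGSeq for the expression analysis, so which tool made the deposited p-values is not settled. The genome build, the strand setting and the treatment of reads that match several places were not given in the sources used here.

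The authors deposited whole-number read counts per gene for 21951 genes, per the file headers, with no normalization; their totals per library are in the report. Beside them the deposited table gives normalized counts, a signal that equals the counts divided by one size factor per library (0.8182 to 1.119), and FPKM values. The FPKM denominator in the deposited table followed the size factor and not the library's total. The authors' log2 fold changes, p-values and adjusted p-values stand in the same table; 2983 adjusted p-values are written as 1 and 4 p-values are missing. The deposited gene length was used only to check the FPKM values. A second deposited table lists FPKM for 46589 genes, of which 24638 are not in the count table. Since the files hold counts, the count test named in the design was the main test, and FPKM served for alternatives.

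Genes were tested with edgeR 4.0.16 in R 4.3.3: trimmed-mean (TMM) scaling, the filterByExpr filter, and the quasi-likelihood F test of ethyl carbamate against control over all 6 libraries with no covariate, two-sided, with Benjamini-Hochberg adjustment over 14705 genes and a threshold of 0.05. The other 7246 listed genes had too few reads. A further count required an absolute log2 fold change of at least 1. Values per group are CPM, computed here from the counts on TMM-scaled library sizes, as mean ± SD of 3 libraries, and the standard error of a log2 fold change is the one that gives the test's F. For genes with 30 reads or fewer in the lower group, the ratio of pooled reads was computed with a 95% exact (Clopper-Pearson) interval, which the text gives for genes with 5 or fewer; such intervals and the floor of 3 counts cover counting error only.

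Before the data were examined, 47 gene lists, the tests, the alternatives and the rule for named genes were fixed. The lists were tested with camera (limma 3.58.1) at a preset correlation of 0.01, with an estimated correlation and with fry beside it, adjusted over the 47 lists. fry asks whether a list's genes move on balance in one direction, and does not compare them with other genes. The rule names the 6 genes that rose and the 6 that fell most among called genes with a symbol, with no overlap between groups and a mean FPKM of at least 5 in the higher group; up to 3 called members per list with the largest absolute change; and 12 stress reporters. The text prints part of these, and marks genes chosen after their values were seen. Of the 166 genes under either heading, 31 overlap a gene on the opposite strand.

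Gene symbols came from RefSeq locus tags for 21580 of 21951 identifiers, and from the Ensembl 115 annotation of WBcel235 for the rest where it had a match; 291 had no match. Coordinates are those of the deposited table, whose build was not given in the sources used here; 16886 of 21656 matched genes lie within 200 bases of the WBcel235 annotation at both ends.

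The alternatives were median-ratio scaling, DESeq2 1.42.0, no filter on low counts, genes with FPKM of at least 5 in 3 libraries, limma on log2 FPKM with pseudocounts of 0.1, 0.5 and 1 (genes with FPKM of at least 1 in 3 libraries), without the trend, with robust variances and after quantile normalization, the replicate number as a block, a threshold of 0.01, and each library left out in turn; scaling by library size only was added after seeing the data. Fold changes on FPKM are on the log2(FPKM + pseudocount) scale, which understates changes of low genes. The scripts were tested on simulated data for this comparison over 14705 genes. With 50 changed genes per size, edgeR recovered 48% at 1.25-fold, 76% at 1.5-fold, 86% at 2-fold and 96% at 4-fold, with 10 false calls (6.13% of calls). The simulated list was found and no other list was called. Genes were simulated independently of each other, so this does not check camera where the genes of a list move together. Few genes were changed in the simulation, so scaling was not checked under a change of 76.3% of the tested genes, as found here. Figures were drawn with matplotlib 3.10.9.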

Results

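RNA from whole wild-type Caenorhabditis elegans, collected as egg-bearing young adults, was sequenced in 6 libraries: 3 from control animals and 3 from animals held in 100 mM ethyl carbamate for 24 h. Ethyl carbamate, also called urethane, is the ethyl ester of carbamic acid and forms in fermented foods and drinks. The control libraries held 19026133 to 22416213 gene counts and the ethyl carbamate libraries 20176242 to 21258740. At least 1 read fell on 17939 to 18506 genes in the control libraries and on 19705 to 19796 genes in the ethyl carbamate libraries. Libraries of the same group had a Pearson r across genes of 0.9918 to 0.9943, and libraries of different groups 0.9286 to 0.9335, although genes are not independent replicates. The first principal component took 89.3% of the variance and separated the groups. Each pair of libraries of a group differed by more than counting noise, with a chi-square of 2.48 to 3.88 per gene. This cannot tell separate animals from separate preparations of the same RNA. All 6 were counted as separate samples because the design text states that the replicates are biological.

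The comparison of exposed with control animals asks how ethyl carbamate changes gene expression in the whole animal. By camera with a preset correlation, the lists of cytochrome P450 and UDP-glucuronosyltransferase genes and of markers of pharynx, neurons and body wall muscle were higher. Those of the proteasome, cytosolic ribosome, propionate shunt, yolk proteins and germline were lower. With correlations estimated from the 6 libraries none of these calls was made. Cuticle collagen genes went both ways and held the largest falls. With edgeR's quasi-likelihood test and Benjamini-Hochberg adjustment, 5876 of 14705 tested genes were higher in ethyl carbamate and 5344 were lower, together 76.3% of the tested genes. Of these, 3504 were at least 2-fold higher and 491 at least 2-fold lower. The 3 exposed and 3 control libraries did not overlap in 77.8% of tested genes, where chance gives 10%. The split between higher and lower depended on the processing. With libraries scaled by size only, 7215 genes were higher and 3409 lower, and the median log2 fold change of all genes lay 0.19 above that of the main analysis. On log2 FPKM of 13917 genes, limma called 5087 higher and 5606 lower with a median of −0.034, and after quantile normalization 3962 and 6132 with a median of −0.11, against 0.05 in the main analysis. The authors' deposited table calls 5361 genes higher and 5357 lower at the same threshold. Of these, 10253 were also called here, all 10253 with the same sign.

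**Figure D1:**
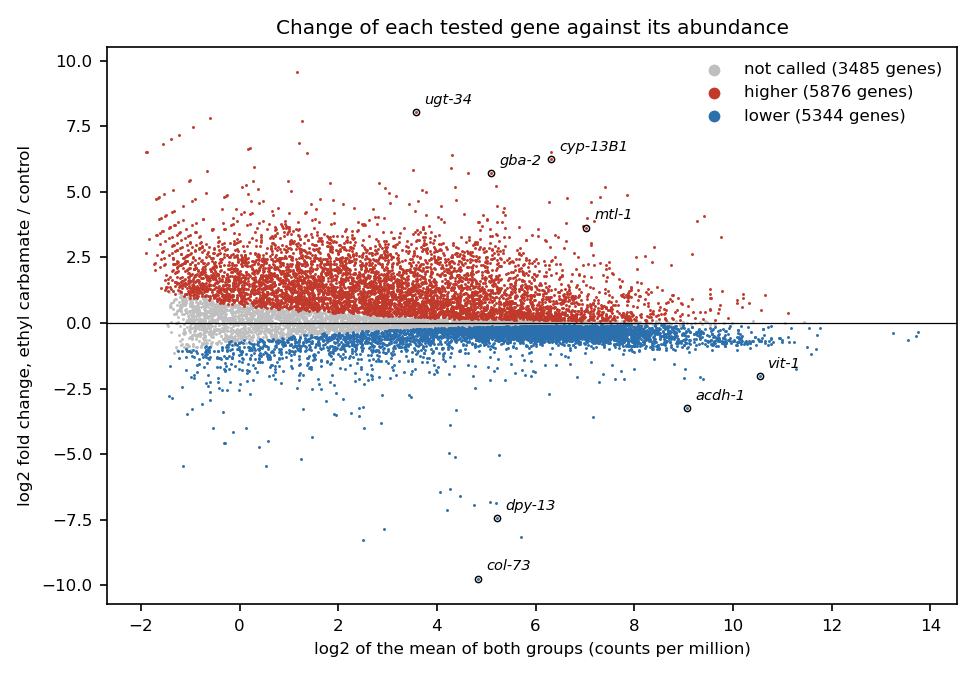
Log2 fold change of each tested gene (vertical axis, ethyl carbamate over control) against the log2 of its mean CPM (counts scaled to library size) over both groups (horizontal axis). Red points are the 5876 genes called higher and blue points the 5344 called lower by edgeR; circles mark named genes, with col-73 the lowest point at a log2 fold change of −9.75.

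Among the named genes chosen by size, cyp-13B1 (F02C12.5, chromosome X, 13406768 to 13409644), a cytochrome P450 gene, rose 75.3-fold, from 2.06 ± 0.27 to 156 ± 3.17 CPM (counts scaled to library size; mean ± SD, n = 3 per group here and below). Its log2 fold change was 6.23 with a standard error of 0.07 (edgeR adjusted p = 3.77e-23). The glucosylceramidase gene gba-2 (C33C12.8, chromosome II, 2182503 to 2186433) rose 52.5-fold to 67.3 ± 1.02 CPM. The UDP-glucuronosyltransferase genes ugt-33 (C35A5.2, chromosome V, 10493406 to 10496468) and ugt-37 (F10D2.6, chromosome V, 7141942 to 7145318) rose 85.1-fold and 40.6-fold. For ugt-34 (F29F11.2, chromosome V, 10654424 to 10656976) the control libraries held 5 reads in all and the exposed libraries 1579, a ratio of 282 with a 95% counting interval of 121 to 871. All 5 lay in control replicate 3, and without it the rise is only bounded, at 302-fold or more against a floor of 3 counts. Without control replicate 2 the ratio is 184. For grd-17 (Y102A5C.34, chromosome V, 16990810 to 16991459), a hedgehog-related locus annotated as a pseudogene, 1 control read stood against 318 reads, a ratio of 284 with an interval of 50.7 to 11300. Without control replicate 2, which held that read, the bound is 61.7-fold, and without control replicate 3 the ratio is 182. The 6 largest falls under the naming rule were all in cuticle collagen genes. Transcripts of col-73 (F11G11.12, chromosome II, 4872098 to 4873127) dropped from 56.8 ± 13.7 CPM to 4 reads over the 3 exposed libraries, a 957-fold fall in pooled reads with an interval of 373 to 3510. Those of col-17 (F11G11.10, chromosome II, 4866436 to 4867574) fell 284-fold and those of dpy-13 (F30B5.1, chromosome IV, 4235614 to 4236706), whose loss makes animals short and fat, fell 174-fold. The others were col-90 (C29E4.1, chromosome III, 7948838 to 7950067), col-41 (T10B10.1, chromosome X, 15175039 to 15176481) and dpy-4 (Y41E3.2, chromosome IV, 14985543 to 14986782), with falls of 142-fold, 122-fold and 118-fold. These 3 overlap a gene on the opposite strand, and the strand setting of the authors' counting was not given in the sources used here.

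**Figure D2:**
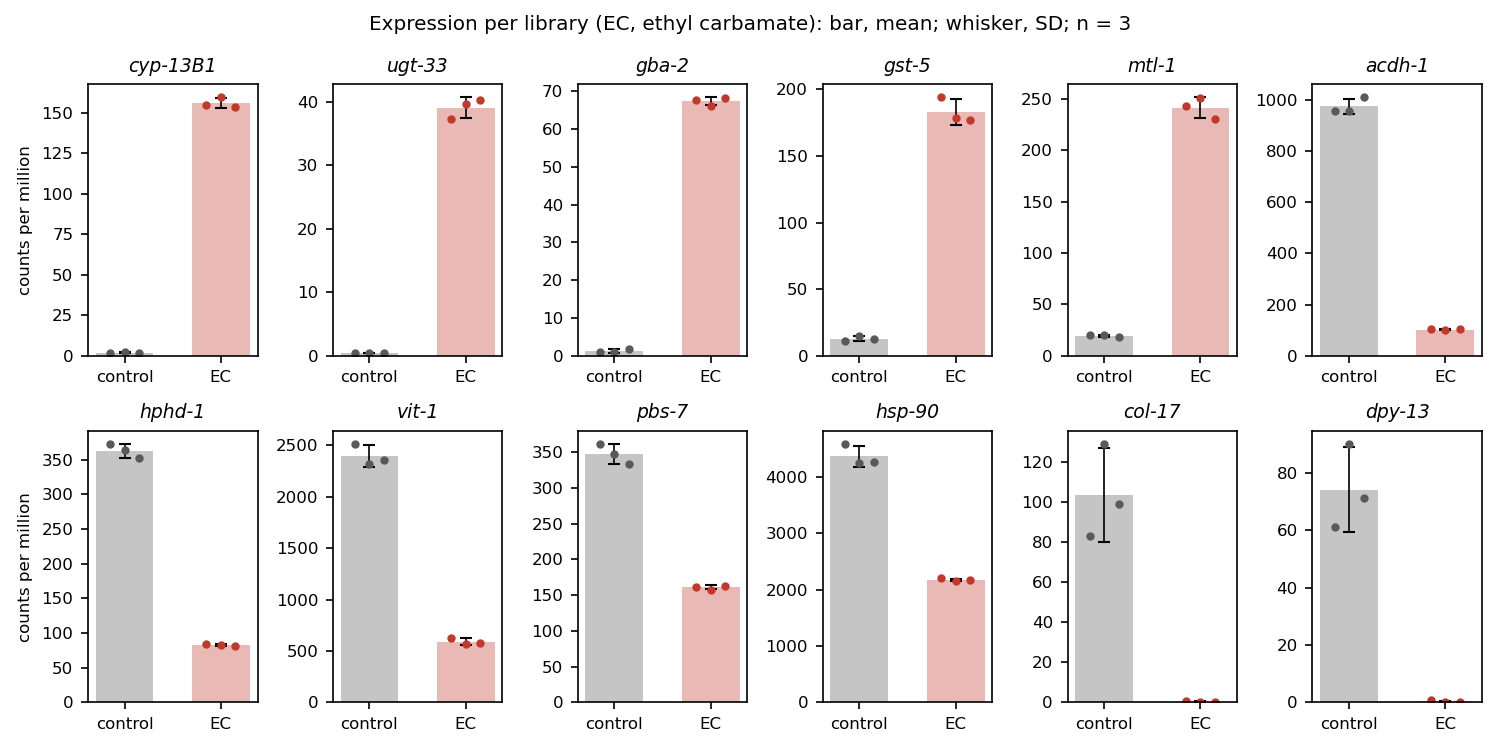
CPM (counts scaled to library size; vertical axes, each from 0) of 12 named genes in the 3 control and 3 ethyl carbamate (EC) libraries; points are libraries, bars means and whiskers SDs. In each panel the 3 exposed libraries lie apart from the 3 controls, as for acdh-1 at 974 ± 30.7 against 103 ± 2.04 CPM.

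Of 7 lists of enzymes and transporters that handle foreign compounds, 4 were called higher with the preset correlation and none with an estimated one. Adjusted p and calls of lists here and below are from camera, which did not compare a list with genes of like abundance. Tested genes of low abundance rose as a whole. Their median log2 fold change was 0.763 at a log2 CPM up to 0 and 0.659 at 0 to 2. Here and below, a rise of that size in a list of such genes is not told apart from this tilt. The test fry, which tests a list against no change and not against other genes, called 18 of the 25 lists that camera did not, among them glutathione S-transferases (0.000365) and ABC transporters (0.00142). Of 62 tested cytochrome P450 genes 43 were higher and 12 lower (camera with the preset correlation, adjusted p = 5.04e-08; adjusted p = 0.0728 with an estimated correlation). Their median log2 fold change was 1.17. On quantile-normalized FPKM 26 were higher and 13 lower of 49, with a median of 0.493. Beside cyp-13B1, the reporter cyp-35A2 rose 4.88-fold to 264 ± 2.89 CPM, and cyp-35A1 went from 3 reads in the controls to 338, a ratio of 101 (counting interval 34.2 to 491; 194 without control replicate 3). Of 64 UDP-glucuronosyltransferase genes, whose products conjugate sugars to such compounds, 43 were higher and 9 lower (camera adjusted p = 7.37e-07; adjusted p = 0.0728 with an estimated correlation). Their median was 0.79, and on quantile-normalized FPKM 0.242, with 26 higher and 16 lower of 56. No control read fell on ugt-35 and 36 exposed reads did, at least 10.7-fold higher against a floor of 3 counts over the group (6.99-fold without control replicate 2 and 6.88-fold without control replicate 3). Short-chain dehydrogenase genes were higher in 16 and lower in 9 of 31 cases (camera adjusted p = 0.0116; adjusted p = 0.241 with an estimated correlation), with dhs-8 up 36.2-fold and dhs-20 up 14.5-fold. This list was not called on log2 FPKM with a pseudocount of 0.1 or 1 (camera adjusted p = 0.141 and 0.146; 0.00125 to 0.241 over 15 camera alternatives). Its median of 0.52 was 0.192 on quantile-normalized FPKM. Esterase genes were higher in 25 and lower in 4 of 37 (camera adjusted p = 0.00176; adjusted p = 0.129 with an estimated correlation; adjusted p = 0.0976 on quantile-normalized FPKM, with 14 higher and 8 lower of 33, and 4.84e-05 to 0.129 over 15 camera alternatives), with the acetylcholinesterase gene ace-3 up 10.2-fold and cest-28 down 5.88-fold. Glutathione S-transferase genes were not called as a list (23 higher, 10 lower of 42; adjusted p = 0.201; 13 higher and 16 lower on quantile-normalized FPKM), but gst-5 rose 14-fold to 183 ± 9.53 CPM. ABC transporter genes (18 higher, 13 lower of 46; adjusted p = 0.713; 10 higher and 20 lower on quantile-normalized FPKM) and alcohol and aldehyde dehydrogenase genes (9 higher, 4 lower of 15; adjusted p = 0.0987; called under 3 of 15 camera alternatives, 0.0221 to 0.444) were not called either, with pgp-14 up 8.75-fold and alh-5 up 6.35-fold. Chosen outside the naming rule after its values were seen, the flavin-containing monooxygenase gene fmo-2 rose 27.3-fold, from 7.08 ± 1.00 to 192 ± 2.82 CPM. In the same libraries the median log2 fold change was 1.32 for neuron markers and −0.44 for germline genes.

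Stress reporters did not move together. Among targets of SKN-1, the factor that drives the oxidative and electrophile response, 13 of 24 were higher and 7 lower (camera adjusted p = 0.194; 8 and 7 on quantile-normalized FPKM, 16 and 5 with scaling by library size), and the reporter gst-4 fell 1.64-fold from 23.8 ± 1.91 to 14.5 ± 0.82 CPM. For gcs-1, the glutamate-cysteine ligase gene, the log2 fold change was −0.13 with a standard error of 0.04 (edgeR adjusted p = 0.00356), and it changed sign to 0.06 with scaling by library size and to 0.0034 with quantile normalization. Among genes with FPKM of at least 5 it was −0.0233 and not called (edgeR adjusted p = 0.552). Targets of DAF-16, the FOXO factor of insulin signalling, were higher in 14 and lower in 1 of 17 cases (camera adjusted p = 4.93e-07; adjusted p = 0.173 with an estimated correlation). The metallothionein gene mtl-1 rose 12.4-fold to 241 ± 10 CPM and the superoxide dismutase gene sod-3 rose 2.76-fold. Antioxidant enzymes as a list were not called, at 12 higher and 10 lower of 30 (adjusted p = 0.573), nor were metal-response genes, at 15 higher and 10 lower of 36 (adjusted p = 0.0757; called under 3 of 15 camera alternatives, 0.0287 to 0.558; 13 higher and 17 lower on quantile-normalized FPKM). Cytosolic heat shock genes fell, with 21 of 28 lower and 3 higher (camera adjusted p = 8.98e-08; adjusted p = 0.159 with an estimated correlation). The chaperone gene hsp-90 fell 2.01-fold, from 4371 ± 187 to 2174 ± 21.6 CPM, hsp-110 fell 2.06-fold, and hsp-16.2 fell 1.61-fold, while hsp-12.3 rose 7.74-fold. For hsp-70 (C12C8.1) the log2 fold change was −0.23 with a standard error of 0.18 (edgeR adjusted p = 0.233), and limma called it on quantile-normalized FPKM. The endoplasmic reticulum chaperone hsp-4 fell 1.31-fold and the mitochondrial chaperones hsp-6 and hsp-60 fell 1.35-fold and 1.52-fold. Their lists were not called, with 11 higher and 11 lower of 23 for the endoplasmic reticulum (adjusted p = 0.961) and 3 higher and 14 lower of 20 for mitochondria (adjusted p = 0.161; called under 2 of 15 camera alternatives, 0.0306 to 0.626; 6 higher and 7 lower with scaling by library size). Osmotic stress genes were higher in 7 and lower in 3 of 11 (adjusted p = 0.265), and gpdh-1, which makes glycerol, fell 2.24-fold while osm-8 rose 6.94-fold. Hypoxia and sulfide response genes were higher in 6 and lower in 5 of 14 (adjusted p = 0.546).

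Protein turnover and synthesis genes fell by small, even steps. Abundant genes fell as a whole, with a median log2 fold change of −0.254 at a log2 CPM of 6 to 8 and −0.404 above 8. The medians of the DNA repair (−0.346), eggshell (−0.387) and germline (−0.438) lists were near that size. Camera did not match on abundance, so these falls are not told apart from the tilt. All 31 proteasome subunit genes were lower (camera adjusted p = 8.47e-24; adjusted p = 0.173 with an estimated correlation), with a median log2 fold change of −0.86, and the 20S subunit gene pbs-7 fell 2.16-fold from 348 ± 13.8 to 161 ± 2.69 CPM. Of 76 cytosolic ribosomal protein genes 74 were lower and 2 higher (camera adjusted p = 1.38e-20; adjusted p = 0.374 with an estimated correlation), with a median of −0.70. On quantile-normalized FPKM 55 were lower and the median was −0.213. The large-subunit gene rpl-14 fell 1.84-fold. DNA damage response and repair genes were lower in 37 and higher in 2 of 44 (camera adjusted p = 1.2e-05; adjusted p = 0.172 with an estimated correlation), and the mismatch repair genes msh-2 and msh-6 fell 1.74-fold and 1.61-fold. Germline and oocyte genes moved in the same direction: 37 of 42 were lower and 2 higher (camera adjusted p = 9.66e-09; adjusted p = 0.374 with an estimated correlation), with pgl-3, a component of germ granules, down 1.80-fold and gld-1 down 1.74-fold. Eggshell genes were lower in 9 of 11 (camera adjusted p = 0.00369; adjusted p = 0.422 with an estimated correlation; adjusted p = 0.947 on quantile-normalized FPKM, with 4 higher and 6 lower, and 0.000361 to 0.947 over 15 camera alternatives), with perm-1 down 1.91-fold. All 6 vitellogenin genes, which encode yolk proteins made in the intestine, were lower (camera adjusted p = 4.47e-07; adjusted p = 0.241 with an estimated correlation; adjusted p = 0.162 on quantile-normalized FPKM, and 5.39e-11 to 0.241 over 15 camera alternatives). Transcripts of vit-1 fell 4.05-fold to 592 ± 33.4 CPM. The vit-2 value, chosen after it was seen, was 1.27-fold lower, and its log2 fold change of −0.34 turned to 0.05 on quantile-normalized FPKM. Genes of early embryos were higher in 6 and lower in 15 of 27 (adjusted p = 0.402), and sperm genes higher in 5 and lower in 6 of 19 (adjusted p = 0.485). Replication-dependent histone genes were higher in 30 and lower in 1 of 38 (camera adjusted p = 0.06; called under 6 of 15 camera alternatives, 0.000225 to 0.422).

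**Figure D3:**
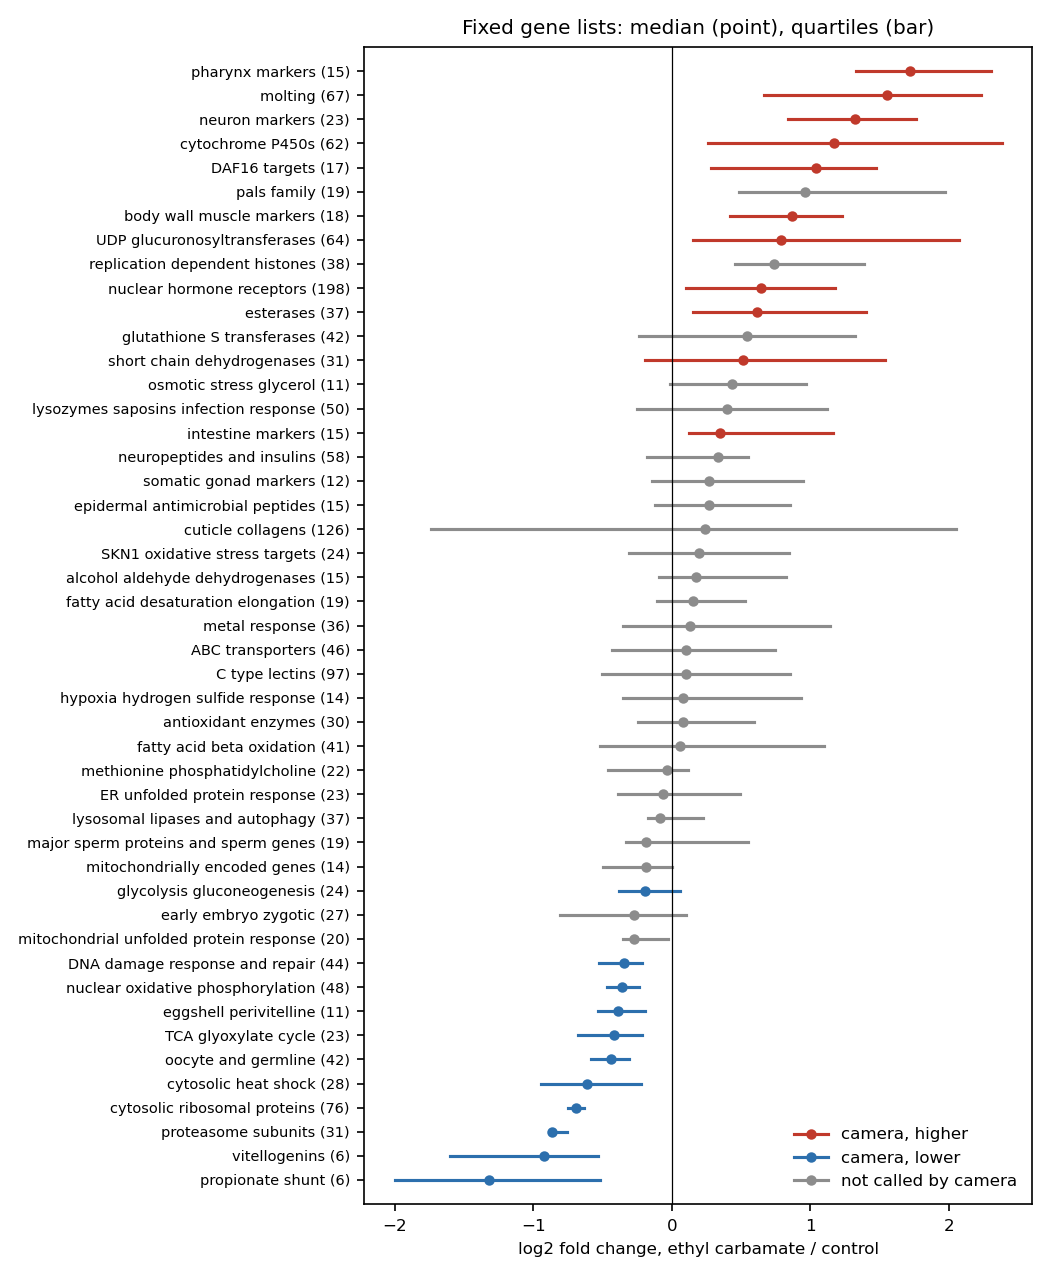
Median (point) and quartiles (bar) of the log2 fold change, ethyl carbamate over control (horizontal axis), of the tested members of each of 47 fixed gene lists (vertical axis, number of tested members in parentheses); red and blue lists were called higher and lower by camera with the preset correlation, grey ones were not. Pharynx markers lie highest at 1.72 and the propionate shunt lowest at −1.32.

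Genes of the propionate shunt, oxidative phosphorylation, the tricarboxylic acid cycle and glycolysis fell as lists, and the other lists of this paragraph were not called. Camera set each list against all other tested genes and not against genes of like abundance. Abundant genes fell as a whole, with a median log2 fold change of −0.254 at a log2 CPM of 6 to 8 and −0.404 above 8. A fall of that size in a list of abundant genes is not told apart from this tilt. All 6 genes of the propionate shunt, which breaks down propionate when vitamin B12 is low, were lower, with a median log2 fold change of −1.32 (camera adjusted p = 8.83e-15; adjusted p = 0.054 with an estimated correlation). The acyl-CoA dehydrogenase gene acdh-1 fell 9.48-fold, hphd-1 fell 4.39-fold to 82.6 ± 0.94 CPM, and hach-1 fell 3.00-fold. Nuclear genes of oxidative phosphorylation were lower in 43 and higher in 2 of 48 (camera adjusted p = 2.06e-07; adjusted p = 0.376 with an estimated correlation; median −0.36, and −0.173 on quantile-normalized FPKM). Genes of the tricarboxylic acid and glyoxylate cycles were lower in 19 and higher in 3 of 23 (camera adjusted p = 2.64e-05; adjusted p = 0.359 with an estimated correlation). The ATP synthase gene asb-1 and the malate dehydrogenase gene mdh-2 fell 1.75-fold and 1.72-fold. Glycolysis and gluconeogenesis genes were lower in 17 and higher in 6 of 24 (camera adjusted p = 0.049; adjusted p = 0.592 with an estimated correlation), while pck-1, the committed step of gluconeogenesis, rose 2.06-fold. The adjusted p missed the threshold without control replicate 1 (0.0552), ethyl carbamate replicate 2 (0.0577) or ethyl carbamate replicate 3 (0.0526), with scaling by library size (0.227), among genes of FPKM 5 or more (0.224) and with quantile normalization (0.867), and ranged from 0.0207 to 0.867 over 15 camera alternatives. Mitochondrially encoded genes were lower in 8 and higher in 2 of 14 (adjusted p = 0.397). Fatty acid beta-oxidation genes were higher in 17 and lower in 18 of 41 (adjusted p = 0.485), with acdh-2 down 30.8-fold and acdh-6 up 7.24-fold. Genes of fatty acid desaturation and elongation were higher in 11 and lower in 5 of 19 (adjusted p = 0.255; called under 1 of 15 camera alternatives, 0.00987 to 0.592), with the fatty acid synthase gene fasn-1 up 2.16-fold. Methionine and phosphatidylcholine genes were lower in 10 and higher in 4 of 22 (adjusted p = 0.0606; called under 2 of 15 camera alternatives, 0.0244 to 0.376), and metr-1, the methionine synthase, fell 1.85-fold while sams-5 rose 2.40-fold. Lysosomal lipase and autophagy genes were higher in 11 and lower in 15 of 37 (adjusted p = 0.893; 18 higher and 2 lower with scaling by library size), with lipl-6 up 9.34-fold and lipl-3 down 3.30-fold.

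Markers of 4 somatic tissues rose, by unequal amounts. Neuron markers were higher in 22 of 23 (camera adjusted p = 5.31e-06; adjusted p = 0.241 with an estimated correlation), with rab-3, a synaptic vesicle GTPase gene, up 4.40-fold. Pharynx markers were higher in 12 and lower in 1 of 15 (camera adjusted p = 1.09e-09; adjusted p = 0.144 with an estimated correlation), with phat-5 up 17.2-fold. Body wall muscle markers were higher in 14 and lower in 2 of 18 (camera adjusted p = 1.3e-07; adjusted p = 0.241 with an estimated correlation), with the myosin gene myo-3 up 4.67-fold to 240 ± 12.5 CPM. Intestine markers were higher in 10 and lower in 2 of 15 (camera adjusted p = 0.00238; adjusted p = 0.321 with an estimated correlation), with a median log2 fold change of 0.35 against 1.72 for pharynx. Somatic gonad markers were not called, at 6 higher and 3 lower of 12 (adjusted p = 0.292). Molting genes were higher in 54 and lower in 6 of 67 (camera adjusted p = 1.08e-13; adjusted p = 0.0728 with an estimated correlation; median 1.55, and 0.741 on quantile-normalized FPKM), with the patched-related genes ptr-22 and ptr-25 up 17.9-fold and 12.1-fold. Cuticle collagen genes were higher in 60 and lower in 55 of 126 (adjusted p = 0.546), with quartiles of the log2 fold change at −1.74 and 2.05. Nuclear hormone receptor genes were higher in 128 and lower in 18 of 198 (camera adjusted p = 0.0459; adjusted p = 0.129 with an estimated correlation), and quantile normalization turned their median from 0.64 to −0.0033. The adjusted p missed the threshold without control replicate 1 (0.052) or ethyl carbamate replicates 1 (0.056), 2 (0.052) or 3 (0.0555), with scaling by library size (0.17) and with quantile normalization (0.458), over a range of 7e-05 to 0.458 for 15 camera alternatives. Neuropeptide and insulin genes were higher in 25 and lower in 8 of 58 (adjusted p = 0.893), but 13 were higher and 21 lower on quantile-normalized FPKM. The largest changes in the list were falls, of 22.7-fold for ins-19 (38.3-fold without ethyl carbamate replicate 2) and 9.69-fold for ins-23, and ins-1 rose 3.32-fold.

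Camera with the preset correlation called none of 4 lists of immune gene families, and fry called all 4 (adjusted p = 5.57e-05 to 0.0146). C-type lectin genes were higher in 39 and lower in 24 of 97 (adjusted p = 0.593; 29 higher and 33 lower on quantile-normalized FPKM), with clec-78 up 11.9-fold. Lysozyme, saposin and other infection-response genes were higher in 25 and lower in 14 of 50 (adjusted p = 0.199; 22 higher and 17 lower on quantile-normalized FPKM), with irg-6 up 13.6-fold to 12.9 ± 0.90 CPM. Members of the pals family, some of which respond to intracellular infection, were higher in 13 and lower in none of 19 (adjusted p = 0.167; called under 2 of 15 camera alternatives, 0.00552 to 0.422), with pals-6 up 9.94-fold (15-fold without control replicate 2). Epidermal antimicrobial peptide genes were higher in 8 and lower in 3 of 15 (adjusted p = 0.526), with cnc-11 up 26.5-fold (43.1-fold without control replicate 3), cnc-2 up 3.10-fold, nlp-29 up 1.48-fold and cnc-7 down 3.17-fold (4.92-fold without ethyl carbamate replicate 1).

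Camera with the preset correlation called 22 of the 47 lists, and with correlations estimated from the 6 libraries it called none, with adjusted p from 0.054 to 0.99 and 11 lists at an unadjusted p under 0.05; fry called 40. Adjusted over the list alone, the number of called members changed in 9 lists, each time by at most 1 gene. Median, mean and test disagreed in sign for antioxidant enzymes, the endoplasmic reticulum and beta-oxidation lists, lysosomal lipases and autophagy, cuticle collagens and sperm genes, and no direction is drawn for these. The majority turned on quantile-normalized FPKM also for antioxidant enzymes (8 higher, 12 lower), cuticle collagens (45 and 57), nuclear hormone receptors (47 and 55), hypoxia genes (6 and 7) and mitochondrially encoded genes (5 and 2). With scaling by library size it turned for methionine (10 and 7), beta-oxidation (20 and 15) and sperm genes (6 and 5), and glycolysis had 9 each way and mitochondrially encoded genes 5. Reads of near-identical copies, as in the vitellogenin, collagen, histone and ugt-33 to ugt-35 genes, could be shared between them, since the handling of such reads was not given in the sources used here. Besides the 3 collagen genes above, dhs-20, gst-5, sod-3, hsp-90, hsp-70, gpdh-1, osm-8, rpl-14 and rab-3 overlap a gene on the opposite strand, whose reads could be counted with theirs.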

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

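All tests in this part were chosen after the results were seen. Outside the count table, the deposited FPKM table lists 1989 genes above 0, each in a single library. The smallest total in the count table is 2 reads; if genes under it were left out, those here hold 1 read each and being in a single library follows from that. There were 461 ± 16 such genes per ethyl carbamate library (445 to 477) against 202 ± 10.2 per control library (195 to 214; mean ± SD, n = 3). The comparisons in the report do not use these genes, and they stood out because their number was above the controls in every exposed library.

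The same tilt held among tested genes. Those under 1 CPM had a median log2 fold change of 0.76, and those above a log2 abundance of 8 had −0.40. Only 1296 of 8541 counted genes under 1 CPM were tested, and the filter can pass such a gene on the reads of 1 group alone. At a log2 abundance of 0 to 2, where nearly all counted genes were tested, the median was 0.659. A background spread evenly over all genes would add the same FPKM at any abundance and dilute abundant genes more. Among all counted genes the median gain was 0.655 FPKM at a log2 abundance of 0 to 2 and 1.44 at 2 to 4. The difference was 0.781 (95% bootstrap interval over genes 0.632 to 0.997). Above these, the medians were −1.64 at 4 to 6, −11.6 at 6 to 8 and −65.3 above 8. Abundance was the mean over all libraries, exposed ones included, which moves genes with a large gain into higher bins. The test therefore cannot decide on such a background. A smaller share of counts in the 10 most abundant genes could lift the rest by at most 0.022 on the log2 scale; this leaves out the other abundant genes, whose fall is part of the pattern. A change in the makeup of the animals' RNA under ethyl carbamate stays open, and was not tested apart from the treatment.

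Markers of neurons, pharynx and muscle rose while germline genes fell. If the whole cause were less germline RNA, somatic markers would rise alike, but the medians of 5 somatic lists spanned 1.45 on the log2 scale. This was above what shuffling their 83 genes gave (permutation test, one-sided, 100000 shuffles, p = 0.0023). Shuffling treats genes as independent, while the estimated correlation within these lists was 0.15 to 0.34, so the p-value is likely too small. The lists were not matched on abundance either, so the test cannot decide on less germline RNA as the whole cause. The gap between neuron and germline medians was 1.75 in the main analysis. A scaling factor per library shifts all log2 fold changes alike, so no choice of factor could change this gap. Quantile normalization can change it, and left a gap of 1.01 (95% bootstrap interval 0.882 to 1.3) on log2 FPKM. That interval resamples genes and not libraries. Less germline RNA, changes within the somatic tissues, more or older embryos inside the animals (raised below), or a mix of these stay open.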

How the results depend on the processing

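Scaling by library size only and the tests below were chosen after seeing the data; the other alternatives were planned. The number of changed genes, 11220, ranged from 7920 (only 10144 genes tested) to 11816, and from 10855 to 11041 with a library left out. Genes called both by the main analysis and by an alternative had the same sign, except 45 with scaling by library size, 142 with quantile normalization and 1 without control replicate 2. Lower genes came to 3409 with scaling by library size. Genes at least 2-fold higher and lower came to 1861 and 187 at FPKM of at least 5, where fewer genes were tested, to 2238 and 298 with limma on log2 FPKM with a pseudocount of 1 (2964 and 464 with 0.1), and to 1571 and 1047 with quantile normalization; these also change tool, measure and genes tested, and the causes were not separated. Camera called 0 lists with an estimated correlation and fry 40. The test fry does not compare a list with other genes, and whether this accounts for the gap was not tested. With a library left out camera called 20 to 23. The replicate numbers do not pair the libraries: deviations from the group means correlated at −0.006, −0.004 and −0.012, and no library correlated best with its own number. With the replicate block 11196 genes and 23 lists were called. Of the named genes' values under alternatives, 3038 kept direction and call, 14 lost the call and 1 gained it. The log2 fold change of gcs-1 turned to 0.0597 with scaling by library size and 0.0034 with quantile normalization, and that of vit-2 to 0.0467 with quantile normalization; the cause was not tested. The replication-dependent histone list was called under 6 of 15 camera alternatives, among them without control replicate 2 (adjusted p = 0.0474; range 0.000225 to 0.422), and the methionine list under 2, among them without control replicate 3 (0.0459; range 0.0244 to 0.376). Of 10 splits of the 6 libraries into 3 and 3, too few for a share under 0.05, the real split called 11220 genes with edgeR and the others at most 0, with 21 to 36 genes at an unadjusted p under 0.05; 6 splits, the real one included, called at least 22 lists and another split 25. Each other split still sets 2 libraries of a treatment against 1, so it keeps part of the contrast.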

Other observations

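The tests in this part, except that of the early embryo list, and the genes named singly were chosen after the results were seen. Gene families by symbol, with at least 10 tested members, gave 143 sets; camera with the preset correlation called 21 higher and 15 lower, and with an estimated correlation 0 (adjusted p 0.281 to 0.999, with 17 at an unadjusted p under 0.05). All 27 cuticlin-like genes (cutl, secreted proteins of the cuticle) were higher, with a median log2 fold change of 2.38 (camera adjusted p = 1.09e-06; adjusted p = 0.281 with an estimated correlation), and cutl-28 went from 2.13 to 22.6 CPM. All 13 bus genes, several of which shape the surface coat, were higher (camera adjusted p = 0.000176; adjusted p = 0.373 with an estimated correlation). Ligand-gated ion channel genes (lgc) were higher in 32 and lower in 1 of 37 (camera adjusted p = 0.0158; adjusted p = 0.404 with an estimated correlation), with lgc-55 at a log2 fold change of 2.58. Genes of the dyf class, needed for sensory neurons to take up dye, were higher in 10 and lower in 1 of 12 (camera adjusted p = 0.0191; adjusted p = 0.356 with an estimated correlation), with dyf-7 at 3.16. Of other families with channel, receptor or sensory genes, unc and inx were called higher (camera adjusted p = 2.39e-11 and 0.0263). The families acr, gcy, twk, npr, mec and osm were not called (camera adjusted p = 0.293, 0.229, 0.146, 0.431, 0.0745 and 0.0901), though most of their members were higher.

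Of the families of nuclear and translation genes, 4 that fell are given here, picked after the results were seen; mdt, taf, gtf and rbm, of the same machinery, were not called (camera adjusted p = 0.195, 0.261, 0.405 and 0.0768). All 25 translation initiation factor genes (eif) were lower, with a median of −0.48 (camera adjusted p = 1.93e-07; adjusted p = 0.317 with an estimated correlation). Nucleoporin genes (npp) were lower in 25 and higher in 1 of 26 (camera adjusted p = 1.97e-06; adjusted p = 0.404 with an estimated correlation), with npp-9, which overlaps a gene on the opposite strand, at −0.68. All 11 Integrator genes (ints) and all 13 prp splicing genes were lower (camera adjusted p = 0.0157 and 0.0187; adjusted p = 0.404 for both with an estimated correlation), with prp-19 at −0.57. The medians of these 4 families, −0.306 (prp) to −0.475 (eif), were near the fall of abundant genes as a whole and are not told apart from it. The medians of cutl, bus, lgc, dyf, eif, npp, ints and prp kept their sign with scaling by library size and with quantile normalization. Several shrank with the latter, to 0.985 for cutl, 0.573 for lgc (1.47 before), 0.83 for dyf (2.37) and −0.11 for prp (−0.306), while those of mdt and taf turned with scaling by library size.

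X-linked genes rose more often than autosomal genes, with 59.9% of 2241 higher against 36.4% of 12450, and medians of 0.51 and −0.04. The X median stayed above the autosomal one with quantile normalization (0.11 and −0.14). Scaling by library size shifts both medians alike (0.70 and 0.16) and could not change their order. Within 20 bins of abundance the difference was 0.33 (95% bootstrap interval 0.284 to 0.381) against 0.546 without bins. Abundance was the mean over all libraries, exposed ones included, which moves genes that rose into higher bins. The test therefore cannot decide whether lower abundance of X-linked genes accounts for all of the difference. Genes are not independent replicates, and what else sets X-linked genes apart was not tested.

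The following genes used in embryos and young larvae were chosen after their values were seen, not from a fixed list. The timing regulators lin-14 and hbl-1 rose 6.20-fold and 10.2-fold, the collagen genes sqt-3, dpy-14 and dpy-17 rose 9.79-fold, 14.9-fold and 16.9-fold, and cut-3 (which overlaps a gene on the opposite strand), hil-7 and noah-1 rose 24.5-fold, 14.8-fold and 4.23-fold. The adult collagen gene col-19 fell 4.16-fold, from 186 ± 9.72 to 44.7 ± 4.53 CPM. A hypothesis is that exposed animals may have held more or older embryos. A set of 26 regulators taken to act in embryos was listed before they were looked up as a set. Whether they act mainly there was not tested. Of these, 21 were higher and 1 lower, with a median log2 fold change of 0.81 (0.36 with quantile normalization). The early embryo list of the report holds 5 of them. That list, fixed before the data were examined, went the other way, with 6 higher and 15 lower of 27. Its median was −0.271 (camera adjusted p = 0.402). It holds genes of early embryos, so its direction cannot decide on older ones. The median of the 26 regulators lay 0.498 above tested genes of like abundance (95% bootstrap interval 0.323 to 0.88). This was just under the 0.5 set for a clear answer and at the 98.3rd percentile of 10000 random lists matched on abundance. Abundance was again the mean over all libraries, exposed ones included. Expression of these regulators in adult tissues cannot be told apart from embryos in whole animals, so the question stays open.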
